A study of Homo sapiens with 6 samples.

How the data were processed

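Poly(A) RNA was sequenced from 6 libraries of LS174T cells, 3 from wild-type cells and 3 whose labels give the genotype FXYD3 knockout. Per the labels' protocols, pelleted cells were lysed in TRIzol and libraries were made with a NEBNext Ultra kit. The submitters' processing notes name HISAT2 version 2.0.5, an aligner, and featureCounts version 1.5.0-p3, a read counter. The annotation, the strand setting of the counter and the handling of reads with several matches are not given in the sources used here. The same notes list a mouse build, mm10, but all 58735 gene identifiers in the deposited table are human Ensembl identifiers. All of them are present in GENCODE release 29, and 58724 have the start and end given there, so coordinates are those of the deposited table on GRCh38.

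The values the authors deposited are counts of reads per gene, whole numbers with no normalization. The table has 58967 rows, of which 232 carry no gene name. Those rows held 0.13 to 0.25% of the counts of a library, and they were left out of library sizes and tests. Columns were assigned to samples through the library name in each sample's description, and groups were taken from the genotype labels. Named genes received 15417232 to 19453217 counts per library. Intervals computed from counts cover counting error only, because reads without molecular identifiers are not independent molecules.

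The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, two-sided) with TMM normalization, a filter by filterByExpr with a minimum count of 10, and robust estimation of the spread. The fit compared the 3 knockout-labelled with the 3 wild-type libraries and had no covariate. It tested 15351 genes, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called. Fold changes are knockout-labelled over wild type throughout. Levels are CPM, counts scaled to a common library size after TMM normalization, computed here from the counts, as mean ± SD over 3 libraries. Because the strand setting is unknown, reads of genes that overlap on opposite strands cannot be told apart, and such overlaps are named beside the gene.

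Before the data were examined, 35 gene lists were fixed for goblet, secretory, absorptive and other cell markers, metabolism, stress and signalling. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. The test was repeated with the correlation estimated per list and with fry, which asks whether a list's genes move one way without setting them against other genes.

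The genes named were also chosen by a rule fixed at that time. It took 14 genes of the design and of goblet cells in any case. Among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups, it took the 8 largest rises, the 8 largest falls and, at an absolute log2 fold change of at least 1, the 5 most abundant in each direction. From each list it took up to 4 called members by smallest p, or the most abundant member where no member was called. Any other gene is said to have been chosen after its values were seen. Some genes are not reported here.

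The alternatives were other normalizations (size factors of DESeq2, upper quartile and total counts), other filters on low counts, DESeq2 1.42.0, limma voom, edgeR without robust estimation, protein-coding genes alone, a test against a minimum change of 1.5-fold, the replicate number as a block, and each library left out in turn. Python 3.11.15 was used for tables, resampling and plots.

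The testing steps were checked on counts simulated with the libraries' own means and depths, with 200 single genes changed and 20 further genes of a list raised by 0.3 on the log2 scale; 15058 of the simulated genes passed the filter. At an adjusted p of 0.05, edgeR recovered 67.2% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 12 of its 178 calls (6.7%) were false and 8 were genes of the raised list. In the same simulation camera called the raised list and 0 of 30 unshifted lists. Its genes were drawn independently of one another and few were changed. The simulation therefore cannot show how often camera calls unshifted lists whose genes are correlated.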

Results

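LS174T is a human colorectal adenocarcinoma line that the labels describe as goblet-like, that is, resembling the mucus-secreting cells of the gut. Its transcriptome was measured in 3 wild-type libraries and in 3 libraries labelled as FXYD3 knockout. FXYD3 is one of the FXYD proteins, small membrane proteins that regulate the Na,K-ATPase. The wild-type libraries held 17585885, 17596549 and 16507805 counts in named genes, and the knockout-labelled ones 15417232, 19453217 and 16581832. Across genes, libraries of one group correlated at Pearson's r of 0.989 to 0.992 in log2 CPM, and libraries of different groups at 0.963 to 0.967. The first principal component carried 70.4% of the variance and separated the groups. No pair of libraries agreed within sampling noise. The labels do not say whether the 3 libraries of a group came from separate cultures or clones, so the p-values measure only the spread between these libraries, which may be technical.

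The targeted gene was examined first. FXYD3 (ENSG00000089356; GRCh38 chromosome 19, 35115879 to 35124324, plus strand) had 54, 91 and 55 counts in the wild-type libraries and 79, 131 and 85 in the knockout-labelled ones. These correspond to 3.88 ± 1.07 and 5.62 ± 0.934 CPM (SD, n = 3 each), a low level in both groups. The log2 fold change was 0.54 (SE 0.20, 95% interval 0.12 to 0.95), with an edgeR adjusted p of 0.0522; the interval reached below 0 without wild-type library 1 (from -0.06) or knockout-labelled library 2 (from -0.10). The FXYD3 transcript was thus not lower where the label says knockout, and every direction below compares libraries by their labels. The counts cover the whole gene and the labels do not describe the edit, so an edit that leaves the transcript in place would not show here. The log2 fold change passed the threshold in 5 other settings, among them without wild-type library 2 (0.79, adjusted p = 0.00313).

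MUC5AC, a gel-forming mucin and one of the 5 most abundant genes called lower by at least 1 log2 unit, fell from 209 ± 16.3 CPM in wild type to 21.3 ± 5.25 CPM in the knockout-labelled libraries (log2 fold change -3.30, SE 0.16, adjusted p = 4.2e-06). Of its gel-forming neighbours on chromosome 11, MUC5B and MUC2 fell, while MUC6, the most abundant of them, went from 395 ± 17.9 to 480 ± 76.5 CPM (adjusted p = 0.0451). MUC5B went from 45.1 ± 3.11 to 15.4 ± 2.38 CPM (log2 fold change -1.55), and MUC2, the main intestinal gel-forming mucin, from 31.5 ± 1.95 to 15.8 ± 3.91 CPM (log2 fold change -0.99, SE 0.13, adjusted p = 3.5e-05). The trefoil peptide gene TFF1 fell from 20.5 ± 2.10 to 5.24 ± 0.798 CPM, and the goblet-cell gene SPINK4 from 10.2 ± 1.94 to 2.18 ± 0.350 CPM. FXYD3 itself was not lower in these libraries.

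Across all genes, 1839 were higher and 1896 lower in the knockout-labelled libraries by edgeR, 24.3% of the 15351 tested. At an absolute log2 fold change of at least 1, 488 were higher and 448 lower. Tested against a minimum change of 1.5-fold, 377 genes were higher and 418 lower.

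**Figure D1:**
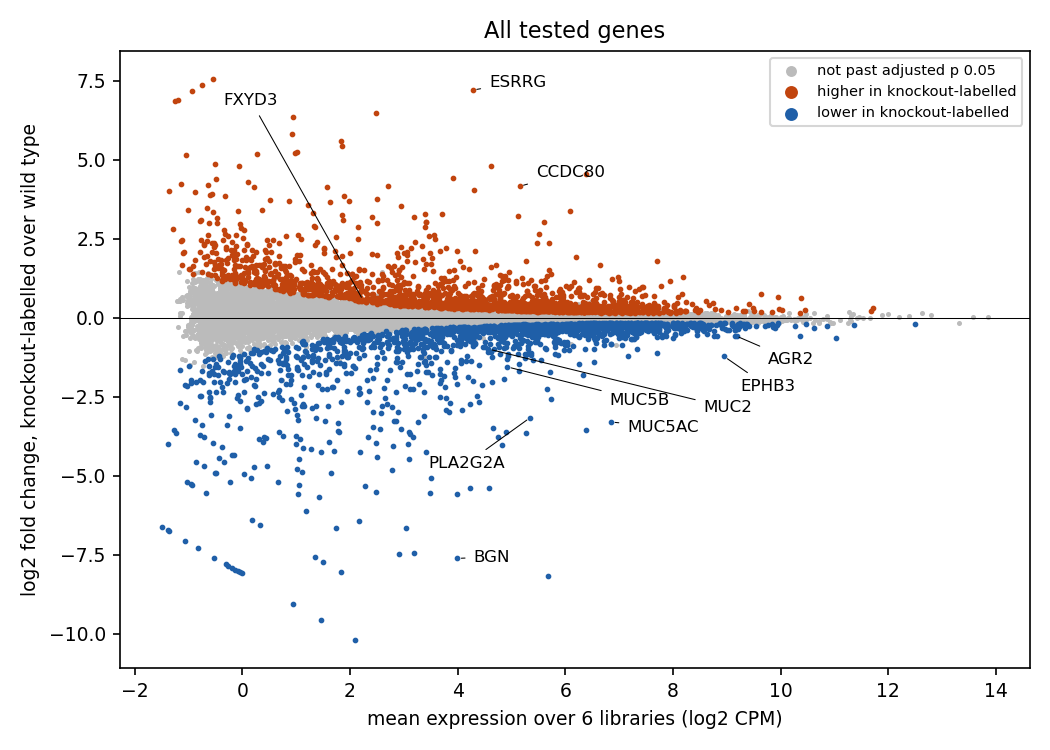
Log2 fold change of knockout-labelled over wild-type libraries against mean expression in log2 CPM, for all 15351 tested genes. Coloured points are the 1839 genes called higher and the 1896 called lower, and FXYD3 lies above 0 among genes of low expression.

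The list of secreted mucins and goblet mucus proteins fell as a group. Of its 17 tested members, 13 were lower, 1 was higher and 3 did not pass; adjusted over the list alone, 14 were lower and 2 higher. Camera gave an adjusted p of 3.51e-06 for the list, and the adjusted p was 0.0807 with an estimated correlation. Besides the genes above, AGR2, a disulfide isomerase of the endoplasmic reticulum involved in mucin production, fell from 680 ± 81.0 to 461 ± 31.1 CPM. FCGBP, a protein of the mucus gel, fell from 31.0 ± 2.10 to 23.9 ± 1.58 CPM. TFF3 was lower by 0.62 on the log2 scale with an adjusted p of 0.0398, a call that was lost on leaving out any 1 of 4 libraries (wild-type 1 or 3, knockout-labelled 2 or 3; adjusted p 0.0507 to 0.173). The member called higher, MUC6, was chosen after its values were seen. Its call was lost under DESeq2, under total-count scaling and on leaving out any library except knockout-labelled 1. CLCA1 had 2 counts in all wild-type and 13 in all knockout-labelled libraries and was too low to test. The gene SPINK4 overlaps BAG1 on the opposite strand, so its reads and those of BAG1 cannot be told apart.

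**Figure D2:**
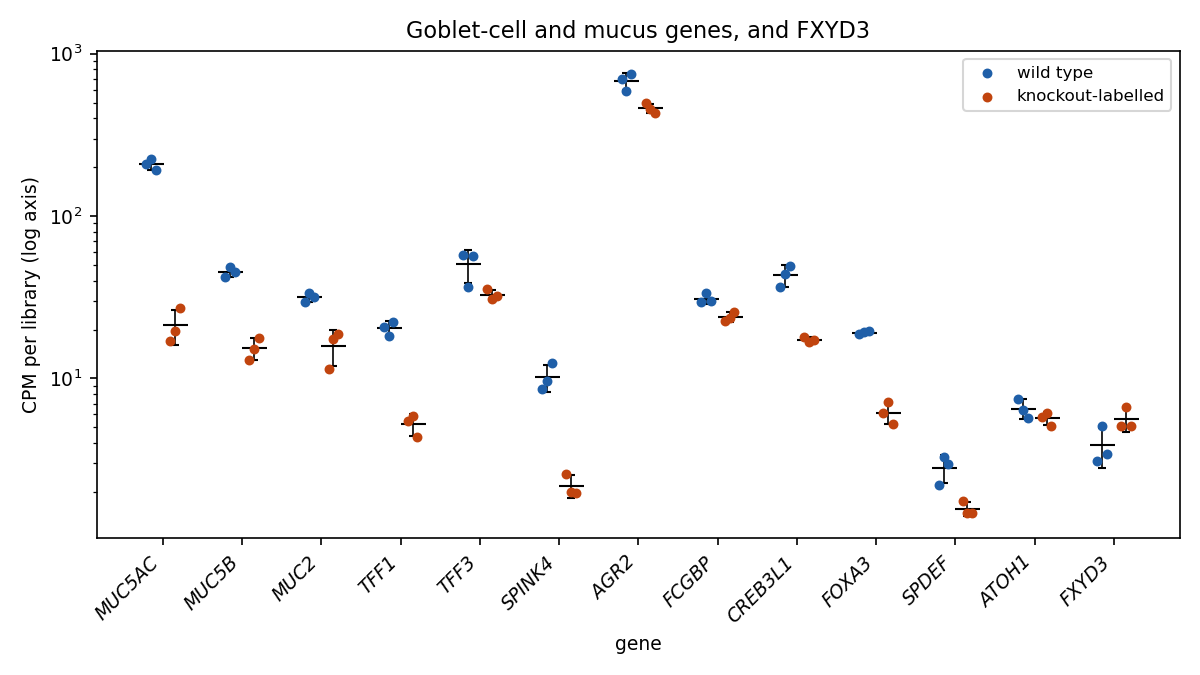
CPM per library on a log axis for 12 goblet and mucus genes and for FXYD3, with the mean and SD of each group of 3 libraries. MUC5AC lay between 193 and 226 CPM in wild type and between 17.1 and 27.2 CPM in the knockout-labelled libraries, while FXYD3 did not separate the groups.

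Transcription factors and ligands of the secretory lineage were lower too. Of 18 tested members of that list, 10 were lower and 0 higher; adjusted over the list alone, 10 were lower and 1 higher. Camera's adjusted p was 0.000142, and the adjusted p was 0.332 with an estimated correlation. FOXA3, a forkhead factor, fell from 19.2 ± 0.388 to 6.17 ± 0.935 CPM, and CREB3L1, a membrane-bound factor of the endoplasmic reticulum that is also in the mucus list, from 43.2 ± 6.60 to 17.4 ± 0.573 CPM. SPDEF, a goblet-cell factor, was low in both groups (2.81 ± 0.550 and 1.57 ± 0.149 CPM, adjusted p = 0.0246), and its call was lost under DESeq2 (adjusted p = 0.0941) and on leaving out any 1 of 4 libraries (wild-type 2 or 3, knockout-labelled 2 or 3). ATOH1, which specifies the secretory lineage, had 6.53 ± 0.917 and 5.69 ± 0.519 CPM, with a log2 fold change of -0.20 (SE 0.16) and an adjusted p of 0.43.

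The Notch ligand genes DLL1 and DLL4 stand in both that list and the Notch list, and their log2 fold changes were -0.92 (SE 0.08) and -1.35 (SE 0.10). In the Notch list 9 of 19 tested members were lower and 4 higher; adjusted over the list alone, 10 were lower and 4 higher. The glycosyltransferase LFNG and the transcription factor RBPJ were among those lower, at -1.19 (SE 0.07) and -0.70 (SE 0.08). Camera gave the Notch list an adjusted p of 0.0324, against an adjusted p of 0.262 with an estimated correlation and 0.0537 without knockout-labelled library 2.

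Genes of cholesterol synthesis and uptake fell as a group, by small amounts. Of 24 tested members 18 were lower and 0 higher; adjusted over the list alone, 19 were lower and 1 higher. Among them were the lanosterol synthase gene LSS (309 ± 7.15 to 215 ± 6.52 CPM), MVD and FDPS. By camera the adjusted p was 2.75e-07, and the adjusted p was 0.0807 with an estimated correlation.

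In the list of glycolysis and hypoxia genes 13 of 29 tested members were lower and 0 higher; adjusted over the list alone, 18 were lower and 1 higher. The members with the smallest p were hypoxia-responsive genes and not glycolytic enzymes. CA9, a carbonic anhydrase, went from 10.1 ± 0.650 to 3.23 ± 0.306 CPM, VEGFA, an angiogenic growth factor, from 313 ± 10.6 to 201 ± 9.23 CPM, and BNIP3 and NDRG1 also fell. For the list, camera gave an adjusted p of 0.000138, and the adjusted p was 0.338 with an estimated correlation. CA9 overlaps ARHGEF39 on the opposite strand, whose own log2 fold change was -0.04.

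Genes of cell cycle and DNA replication fell as a group. Of 32 tested members, 12 were lower and 1 higher; adjusted over the list alone, 16 were lower and 1 higher. CCNE1, which encodes cyclin E1, changed by -0.50 (SE 0.09), the replication-licensing gene CDC6 by -0.35 (SE 0.06) and the helicase subunit gene MCM5 by -0.32 (SE 0.06) on the log2 scale. The camera adjusted p was 0.000267, with an adjusted p of 0.186 with an estimated correlation. The median log2 fold change of the list was -0.14.

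Among antimicrobial genes, PLA2G2A, a secreted phospholipase, fell from 73.3 ± 5.01 to 8.22 ± 0.459 CPM and LCN2, an iron-siderophore binding protein, from 23.5 ± 2.83 to 6.91 ± 0.482 CPM, while REG1A rose from 9.50 ± 1.24 to 27.5 ± 1.70 CPM. In the antimicrobial list 6 of 9 tested members were lower and 1 higher, the same numbers as adjusted over the list alone, with a camera adjusted p of 0.0368 and an adjusted p of 0.338 with an estimated correlation. That call was lost without wild-type library 3 (adjusted p = 0.0967), without knockout-labelled library 2 (0.0537) and with the replicate block (0.052). Of 5 tested Paneth cell markers 4 were lower (PLA2G2A, PRSS2, PNLIPRP2 and REG3A) and 0 higher, the same as adjusted over the list alone. Camera's adjusted p for them was 0.00205, with an adjusted p of 0.186 with an estimated correlation and 0.0723 with no filter on low counts. PLA2G2A and REG3A are in both lists, and PRSS2 belongs to a family of near-identical trypsinogen genes, so its counts are uncertain. Apart from PLA2G2A, the Paneth markers called lower were low in wild type too. PRSS2 had 86 counts in all wild-type libraries together and 4 in all knockout-labelled ones, PNLIPRP2 126 and 53, and REG3A 51 and 9.

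Chaperone and stress genes fell in part. In the list of the unfolded protein response 8 of 34 tested members were lower and 0 higher, as also adjusted over the list alone, led by CHAC1 (log2 fold change -0.98, SE 0.08), TRIB3 (-0.54, SE 0.06) and ATF4 (-0.36, SE 0.06), the last a stress-induced transcription factor. The list had a camera adjusted p of 0.0361, and the adjusted p was 0.6 with an estimated correlation. In the heat shock list 5 of 17 tested members were lower and 0 higher, as also adjusted over the list alone, with FKBP4 at -0.25 (SE 0.06). The camera adjusted p was 0.0368, and the adjusted p was 0.6 with an estimated correlation. Both calls were lost with the replicate block (adjusted p = 0.052 and 0.0552) and without wild-type library 3 (0.113 and 0.0967), knockout-labelled library 2 (0.0576 and 0.0613) or knockout-labelled library 3 (0.111 and 0.128). Fry called neither list (adjusted p = 0.0552 and 0.0732).

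There were 3 lists called higher. In the interferon response list 16 of 30 tested members were higher and 3 lower; adjusted over the list alone, 17 were higher and 4 lower. OAS3, an antiviral enzyme, rose from 99.2 ± 4.30 to 158 ± 10.1 CPM and IFI27 from 41.9 ± 5.32 to 78.0 ± 9.35 CPM, whereas BST2, a membrane protein that tethers viruses, fell from 23.5 ± 3.79 to 4.06 ± 0.252 CPM. Tested by camera, the list had an adjusted p of 0.00341, and the adjusted p was 0.338 with an estimated correlation. In the list of NRF2 targets and glutathione genes 8 of 22 tested members were higher and 0 lower, as also adjusted over the list alone (adjusted p = 0.00341 by camera; adjusted p = 0.274 with an estimated correlation). Its leading members were aldo-keto reductases, with AKR1B10 rising from 12.1 ± 0.615 to 36.8 ± 2.91 CPM and AKR1C3 from 47.4 ± 2.35 to 77.7 ± 2.44 CPM. AKR1C1 and AKR1C2 also rose, but they share most of their sequence and their separate counts are uncertain. Of 23 tested p53 targets 9 were higher and 1 lower, and adjusted over the list alone 10 were higher and 1 lower. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 349 ± 13.3 to 464 ± 17.6 CPM, SESN1 and SPATA18 rose, and BTG2 fell. In the camera test the adjusted p was 0.0123, with an adjusted p of 0.205 with an estimated correlation.

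**Figure D3:**
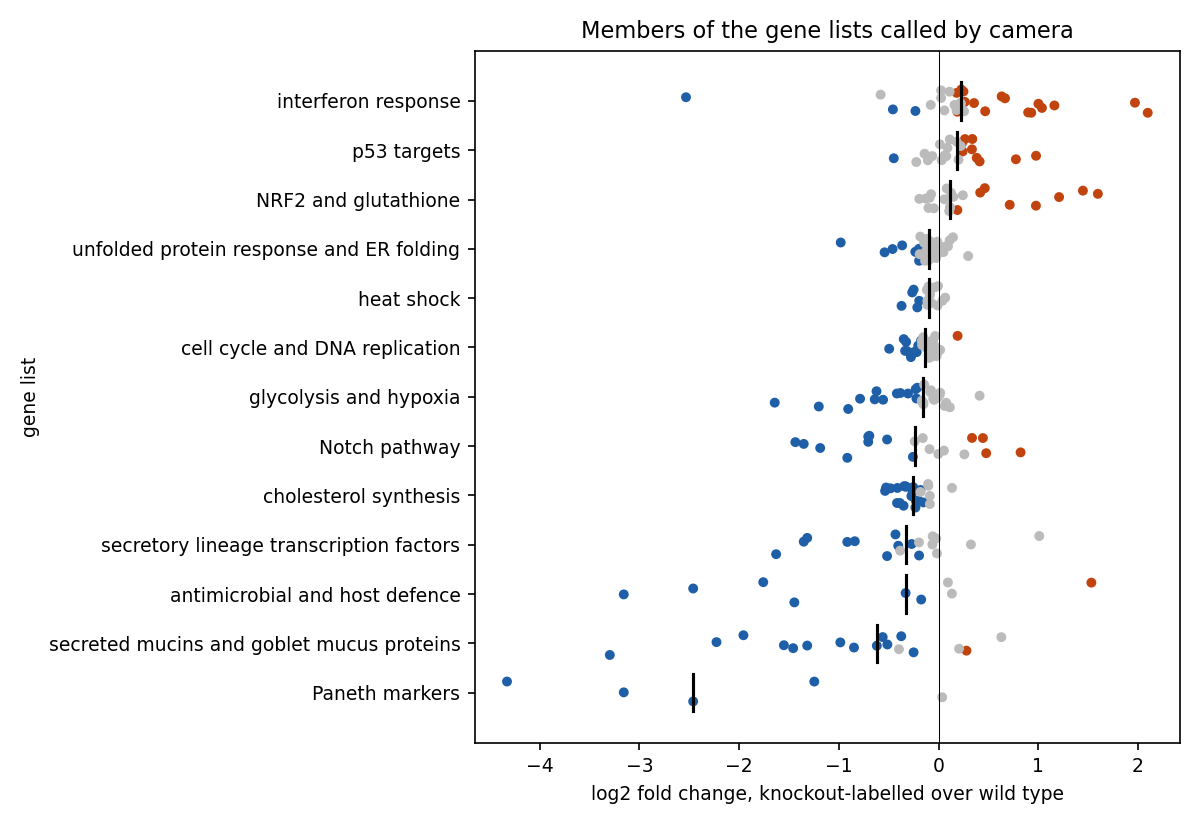
Log2 fold change of each tested member of the 13 lists called by camera at the preset correlation, one point per gene, with a vertical bar at the list's median. Orange points are genes called higher, blue points genes called lower and grey points genes that did not pass; 10 lists were lower and 3 higher, and with an estimated correlation 0 lists were called, 6 having an unadjusted p below 0.05, against 19 lists called by fry, among them 11 of these 13.

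The sodium pump was measured because FXYD proteins bind it. ATP1B3, a gene of its beta subunits, fell from 293 ± 3.17 to 255 ± 8.30 CPM. ATP1B1 went from 1237 ± 10.96 to 1386 ± 27.4 CPM with an adjusted p of 0.0373, a call that was lost with the replicate block and on leaving out any library except wild-type 2. FXYD5 had a log2 fold change of 0.18 (SE 0.07) and an adjusted p of 0.0897, passing only without wild-type library 3 (0.24, adjusted p = 0.0172). Of the 4 tested genes of the list 2 were higher and 1 lower, and adjusted over the list alone 3 were higher and 1 lower; so few members were not tested as a list. Among other transporters, AQP3, a water and glycerol channel, fell from 46.0 ± 4.83 to 12.1 ± 0.781 CPM and SCNN1A, a subunit of the epithelial sodium channel, from 133 ± 4.57 to 82.1 ± 4.69 CPM. SCNN1A overlaps LTBR on the opposite strand. In that list 5 of 18 tested members were higher and 8 lower (camera adjusted p = 0.235).

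Intestinal stem cell and Wnt target genes changed strongly in both directions, with 8 of 21 tested members higher and 7 lower and a camera adjusted p of 0.79. OLFM4, a crypt stem cell marker, fell from 29.9 ± 2.58 to 3.99 ± 0.689 CPM, SMOC2 from 53.8 ± 4.13 to 16.8 ± 2.14 CPM and the receptor gene EPHB3 from 692 ± 9.57 to 297 ± 17.7 CPM. NOTUM, a Wnt-inactivating enzyme, rose from 6.03 ± 1.54 to 25.9 ± 2.61 CPM. Transmembrane mucins also went both ways. MUC17 rose from 28.8 ± 2.92 to 72.8 ± 12.6 CPM and MUC3A by 0.80 on the log2 scale (SE 0.08), and MUC13 fell from 339 ± 23.8 to 294 ± 9.55 CPM, a call lost without wild-type library 3 or knockout-labelled library 2. MUC3A has close relatives beside it on chromosome 7, which makes its counts uncertain. For that list 2 of 6 tested members were higher and 1 lower (camera adjusted p = 0.0723, and 0.0208 with no filter on low counts).

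Camera called none of the remaining lists at the main settings. Fry, which does not set a list against other genes, called 6 of them, namely O-glycosylation (higher, adjusted p = 0.0285), junctions (lower, 0.00192), immediate early genes (higher, 0.0115), mesenchymal genes (higher, 1e-04), secretory transport (higher, 0.00628) and enteroendocrine markers (lower, 0.0222), as well as the transmembrane mucins (higher, 0.00116) and transporters (lower, 0.00628). Enzymes of mucin-type O-glycosylation had 9 of 28 tested members higher, among them GCNT3 (110 ± 2.17 to 174 ± 4.23 CPM), and 6 lower, among them GALNT12 (6.09 ± 0.513 to 0.199 ± 0.109 CPM). Their median log2 fold change was 0.02 and their mean -0.05, so the sign depends on the summary, and camera's adjusted p was 0.375. Among junction genes 9 of 27 were lower, including CLDN1 and CLDN3, and 2 were higher (adjusted p = 0.178). Absorptive cell markers had 4 of 17 higher and 6 lower, with CEACAM5 falling from 31.1 ± 2.42 to 11.1 ± 1.498 CPM, CDX1 falling from 190 ± 14.2 to 119 ± 8.72 CPM and DPP4 rising from 24.97 ± 2.26 to 57.4 ± 1.56 CPM (adjusted p = 0.441). Immediate early and MAPK feedback genes had 7 of 25 higher and 4 lower, with JUN and DUSP6 higher and DUSP4 lower (adjusted p = 0.288). Inflammatory targets of NF-kB had 3 of 20 higher and 6 lower, with CXCL1 higher and CCL20 and CXCL2 lower (adjusted p = 0.288). Mesenchymal genes had 4 of 11 higher, with the smallest p for COL5A1, and 3 lower (adjusted p = 0.151).

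For calcium handling genes 5 of 25 were higher and 5 lower (camera adjusted p = 0.722), and for secretory transport and exocytosis genes 5 of 28 were higher and 2 lower (adjusted p = 0.689). Autophagy and lysosome genes had 2 of 27 higher and 3 lower (adjusted p = 0.79), with a median of -0.03 and a mean of 0.02. Nuclear genes of oxidative phosphorylation had 1 of 41 higher and 5 lower and mitochondrial mRNAs 5 of 13 higher and 1 lower (adjusted p = 0.0723 for each). Cytosolic ribosomal protein genes had 0 of 36 called by edgeR, DESeq2 or limma voom, with 2 at an unadjusted p below 0.05 in edgeR (camera adjusted p = 0.269). The most abundant of them, RPS2, had a log2 fold change of -0.01 (SE 0.07), whose sign changed with the scaling. Without wild-type library 2 camera called the ribosomal list lower (adjusted p = 0.000123) and also oxidative phosphorylation (0.000764), which was called lower without knockout-labelled library 1 (0.0386) and with no filter on low counts (0.0162) too. Mitochondrial mRNAs were called higher without wild-type library 1 (0.0357). Enteroendocrine markers had 2 of 5 higher and 1 lower, with a median of 0.75 and a mean of -0.22 (adjusted p = 0.697), and tuft cell markers 1 of 6 higher and 2 lower (adjusted p = 0.816). Of markers of other cells, 1 of 3 tested leukocyte genes was lower (CD14, 189 against 20 counts) and 1 of 4 tested fibroblast and endothelial genes was higher (COL3A1, 16 against 293 counts), lists too short to test; with no filter on low counts camera called the fibroblast and endothelial list, then of 11 members, higher (adjusted p = 0.0162), and the leukocyte list had an adjusted p of 0.113. Replication-dependent histones, which lack poly(A) tails, had 2 of 9 higher (adjusted p = 0.151). Mitochondrial ribosomal RNA took 1.27 to 1.43% of counts in wild type and 1.12 to 1.14% in the knockout-labelled libraries. Among genes beside FXYD3 on chromosome 19, 1 of 8 was higher (GRAMD1A, 3.09 ± 0.947 to 11.7 ± 1.08 CPM) and 1 lower (CD22), with a camera adjusted p of 0.441. CD22 lost its call under DESeq2 and on leaving out any 1 of 3 libraries (wild-type 2, knockout-labelled 1 or 3). DMKN, which is not in that list and was chosen after its values were seen, lies at 35497220 to 35513658 on chromosome 19. It fell from 20.1 ± 1.46 to 1.05 ± 0.123 CPM (edgeR adjusted p = 4.8e-17). Adjusted over the list alone, the counts of the lists in this paragraph and the 2 before it were the same, except for 10 higher among stem cell and Wnt genes, 5 higher among absorptive cell markers, 8 higher among immediate early genes, 6 higher among mitochondrial mRNAs, 2 higher among tuft cell markers and 4 lower in oxidative phosphorylation.

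The largest rises and falls reached many-fold changes. ESRRG, an orphan nuclear receptor, went from 0.256 ± 0.0765 to 38.6 ± 1.17 CPM, the magnesium channel gene TRPM6 from 1.71 ± 0.206 to 47.8 ± 3.85 CPM, and the cystatin gene CST1 from 6.78 ± 1.61 to 160 ± 11.1 CPM. CCDC80, GUCY1A1, CD200, TBKBP1 and MEF2C completed the 8 largest rises. In the other direction, BGN, which encodes the proteoglycan biglycan, went from 1621 counts in the wild-type libraries together to 8 in the knockout-labelled ones, LIMCH1 from 768 to 4, RIN3 from 923 to 5 and TCEAL9 from 831 to 8. NID1, a basement membrane gene, went from 31.3 ± 2.04 to 0.651 ± 0.191 CPM, and SH3GL3, ARHGAP6 and BEX3 completed the 8 largest falls. Among the abundant genes changed by at least 1 log2 unit, FAM84A (169 ± 5.34 to 411 ± 7.25 CPM), VCAN, COL17A1, SERPINB5 and CALB1 were higher. EPHB3, FGFBP1, MUC5AC, S100P (199 ± 33.7 to 86.6 ± 5.47 CPM) and TP53I11 were lower. All of these were called by edgeR and, as the rule that chose them requires, showed no overlap between the 3 libraries of each group. Further overlaps on the opposite strand, whose reads cannot be told apart, are those of DLL1 with FAM120B, FDPS with RUSC1-AS1, GCNT3 with GTF2A2, LSS with AP001469.1, HSP90AA1 with WDR20, ATP1B1 with NME7, ATP1B3 with ATP1B3-AS1, BGN with HAUS7 and VCAN with VCAN-AS1.

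**Figure D4:**
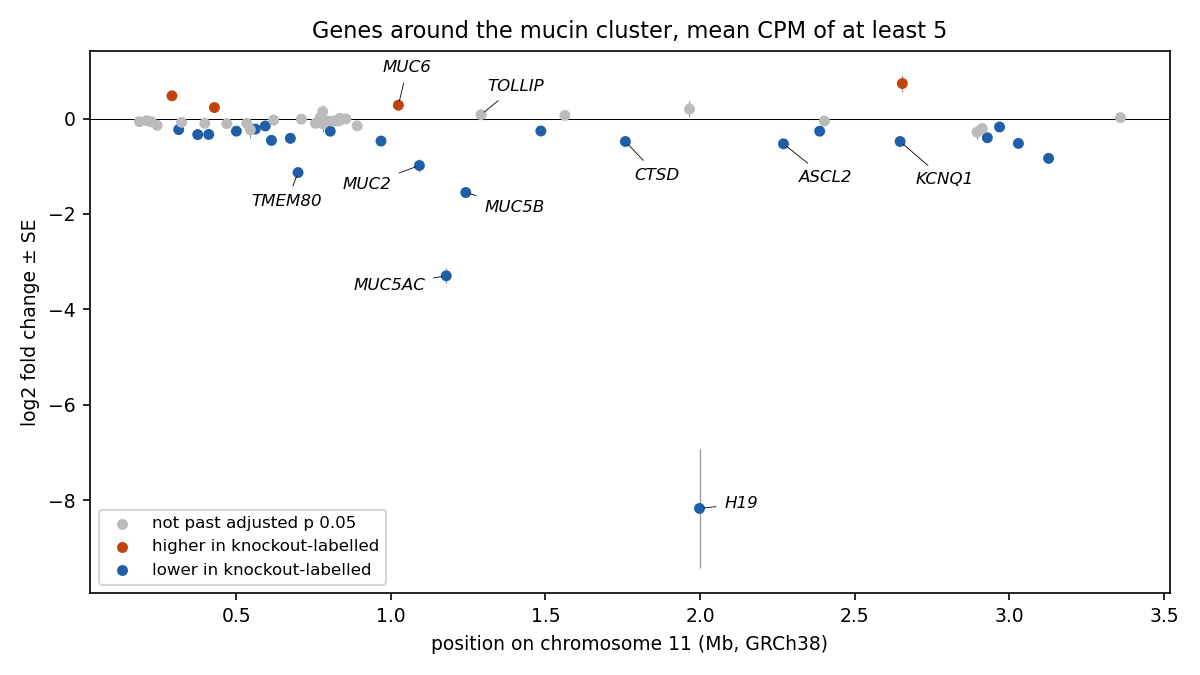
Log2 fold change with its standard error against position on chromosome 11 in Mb (GRCh38), for genes with a mean of at least 5 CPM around the mucin cluster; orange points were called higher, blue points lower and grey points did not pass. MUC2, MUC5AC and MUC5B lie below 0 at -0.99, -3.30 and -1.55, and the neighbouring mucin MUC6 lies above 0 at 0.28.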

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

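The tests in this part were chosen after the result was seen. Rows of the table without a gene name, which no comparison used, held a larger share of the counts in the knockout-labelled libraries: 0.216, 0.23 and 0.25%, against 0.134, 0.15 and 0.13% in wild type, a ratio of group means of 1.681. The Wilson 95% intervals of the shares ran from 0.128 to 0.152% over the wild-type libraries and from 0.214 to 0.252% over the knockout-labelled ones. Of 154 such rows with at least 60 counts, 54 had all knockout-labelled libraries above all wild-type ones and 14 had all of them below, where chance gives 5% each way, and 10 rows made up 81.6% of the net rise. More intergenic or genomic DNA background would add reads to every row and so raise the typical row by at least the ratio of the whole share, but the median ratio over the 154 rows was 1.182 (95% bootstrap interval 1.08 to 1.29), which argues against it as the whole cause. A first test of the same explanation, the share of counts in pseudogenes, gave a ratio of 1.034 (SD 0.040) and was set aside because a high baseline in pseudogenes could hide a small added share. Genes of the lincRNA, antisense and sense-intronic types together held a larger share of named-gene counts in each knockout-labelled library (0.829 to 0.872%, against 0.705 to 0.752%). A smaller contribution of background therefore stays open. Rows assembled mainly from reads of the knockout-labelled libraries cannot be told apart from a difference in transcription that goes with the label, since 79.4% of the separated rows were higher and the sources used here do not say which libraries the rows were built from.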

How the results depend on the processing

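The alternatives were fixed before the data were examined. Over other normalizations, filters, tools and libraries left out, between 2711 and 4590 genes were called (3735 with the main settings), 70 to 99.4% of the main calls were called again, and 0 of those shared calls turned direction. The share of calls that were higher stayed between 44.7 and 55.4%, and other scalings moved the median log2 fold change to at most 0.027. Leaving out 1 library gave 1329 to 2189 genes higher and 1376 to 2401 lower. DESeq2 called 2946 genes. Against a minimum change of 1.5-fold, 377 genes were higher and 418 lower, because that test asks for a larger change. With a mean count of at least 50, 197 and 205 genes were higher and lower at an absolute log2 fold change of at least 1, because fewer genes of low count were tested. The log2 fold change of FXYD3 passed the threshold with upper quartile scaling (0.557), no filter on low counts (0.524), protein-coding genes alone (0.546) and the replicate block (0.543), and ranged from 0.382 to 0.788 with 1 library left out; its adjusted p ran from 0.00313 to 0.273 over all settings, and the cause was not tested. No call of lists held with an estimated correlation (0 lists, against 13 with the preset one), and 9 to 15 lists were called with 1 library left out. The estimated correlation was above the preset 0.01 for some called lists, such as secretory lineage factors (0.191), and below it for others. It was -0.0246 for cholesterol synthesis and -0.0125 for secreted mucins. For those lists a higher correlation does not account for the lost call. The unadjusted camera p of cholesterol synthesis went from 8.6e-09 at the preset correlation to 0.00308 with the estimated one. The loss of all calls therefore cannot be read as an effect of correlation alone. The log2 fold change of RPS2, near 0 and not called, turned to 0.014 with upper quartile scaling, 0.019 with total counts, 0.003 with a mean count of 50 and 0.003 with protein-coding genes, and ran from -0.074 to 0.055 with 1 library left out, and the log2 fold change of TCEAL4, also not called, ran from -0.098 to 0.04 with 1 library left out; the cause was not tested for either. For single named genes, 1848 values kept their side of the threshold and 18 lost it under other settings, and 972 kept it, 56 lost it and 1 gained it with 1 library left out. Replicate numbers did not pair the libraries: same-numbered libraries deviated together with correlations across genes of 0.023, -0.075 and -0.096. The replicate block called 1478 genes higher and 1475 lower and 10 lists; apart from the calls given in the report, those it ended for single genes were ATP6V1H, HSP90AA1 and TPH1. Depth limits genes of low count most, such as FXYD3 with 54 to 131 counts per library.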

Other observations

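Apart from COL17A1, COL5A1, BEX3, TCEAL9, CD200, CCDC80 and ATG3, which the fixed rule took, the genes in this paragraph and the next were chosen after their values were seen, from a look over all genes for large changes and for neighbours that moved together; more genes were looked at than are given. Tests are those of edgeR as in the report. Wnt-related genes outside the rule for named genes also went both ways: LEF1, a transcription factor of the Wnt pathway, rose from 2.29 ± 0.965 to 19.1 ± 2.03 CPM, SP5 rose from 2.25 ± 0.247 to 9.01 ± 1.54 CPM, and LGR5, a stem cell receptor, fell from 47.7 ± 2.37 to 21.8 ± 1.73 CPM (SD, n = 3 libraries labelled by genotype). The collagen gene COL18A1 fell from 53.5 ± 1.18 to 3.25 ± 0.198 CPM and PXDN, a matrix peroxidase, from 71.2 ± 3.98 to 5.63 ± 0.687 CPM, whereas other matrix genes rose, COL17A1 from 73.2 ± 1.39 to 178 ± 3.62 CPM and COL5A1 from 12.5 ± 0.448 to 40.1 ± 1.75 CPM. The cell adhesion gene PCDH7 rose from 11.9 ± 0.644 to 124 ± 7.51 CPM. PAGE1 and MAGEA1 are cancer-testis genes, usually silent outside the germ line; PAGE1 fell from 154 ± 22.3 to 13.1 ± 0.660 CPM and MAGEA1 rose from 1.77 ± 1.20 to 16.5 ± 0.513 CPM.

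Some neighbouring genes changed together. On the X chromosome, between 103252995 and 103378077 of GRCh38, BEX2 had 360 counts in the wild-type libraries together and 1 in the knockout-labelled ones, a ratio of counts, knockout-labelled over wild type, of 0.00274 (95% counting interval 6.9e-05 to 0.0154), BEX3 had 1873 and 45, TCEAL9 831 and 8, and TCEAL8 fell from 45.2 ± 2.95 to 27.8 ± 0.862 CPM. The stretch did not extend to TCEAL4, the next tested gene (103576231 to 103587736), at 45.3 ± 3.29 and 44.0 ± 4.37 CPM (edgeR's adjusted p = 0.797). On chromosome 3, CD200, ATG3, SLC35A5 and CCDC80, which lie between 112332347 and 112649530, were all higher, by log2 fold changes of 4.05, 0.94, 0.68 and 4.16; ATG3 and SLC35A5 overlap on opposite strands. The imprinted RNA H19 (chromosome 11, 1995176 to 2001470) had 2830, 1956 and 534 counts in the wild-type libraries and 5, 8 and 5 in the knockout-labelled ones (log2 fold change -8.18, SE 1.25, adjusted p = 0.0137), a call lost on leaving out any knockout-labelled library (adjusted p 0.0663 to 0.0724). Of 711 genes on the autosomes and the X chromosome with a mean of at least 1 CPM that were called at an absolute log2 fold change of at least 1, 62 adjacent, non-overlapping pairs changed in the same direction. Shuffling the changes within chromosomes gave 15.5 such pairs on average and at most 29 in 1000 permutations (permutation p = 0.001, the smallest they can give); adjacent genes include paralogs, and no cause was tested.

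The tests in this and the following paragraphs were chosen after the results were seen, except that of long transcripts, whose prediction was written first. The FXYD3 transcript was not lower where the label says knockout. An exchange of single libraries between the groups would leave libraries closer to the other group, but 0 of 6 correlated better with a library of the other group than with its own. A minority of unedited cells among cells that had lost the transcript would give a log2 fold change below -1, but its 95% interval began at -0.099 or above with any 1 library left out. A majority of unedited cells cannot be told apart, since the interval began at 0.123 with all libraries but at -0.06 without wild-type library 1 and at -0.099 without knockout-labelled library 2. A complete exchange of the labels, with the transcript lost in the edited cells, would leave the wild-type-labelled libraries little FXYD3. Their level was 0.69 of the knockout-labelled one, lower but not as low as that. The limits set for this ratio left the exchange undecided. The 95% interval of the log2 fold change, looked at besides, ended at 0.95, or at 1.222 without wild-type library 2. Both ends are short of the rise that a lost transcript would give, which argues against such an exchange. An exchange in which the edited cells kept the transcript, or were mixed with many unedited cells, cannot be told apart. The neighbouring gene LGI4 had 7.3% as many counts as FXYD3. An edit that disrupts the protein and leaves the transcript in place may also give this pattern, and it was not tested because the counts cover the whole gene.

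MUC2, MUC5AC and MUC5B, which lie between 1074875 and 1262172 on chromosome 11, were all lower. Loss of a copy of the surrounding region would lower its other genes by about 0.4 or more on the log2 scale, but the median log2 fold change of the 25 other genes within 500 kb with a mean of at least 5 CPM was -0.051 (95% bootstrap interval -0.16 to -0.01), and loss of equal copies of the 3 genes alone would lower them alike where alleles are expressed alike, but their log2 fold changes differed by up to 2.312 (SE 0.206). A loss of long transcripts through RNA quality would lower other long genes, but the median over 1382 genes with an exon length of at least 10 kb was 0.071 (95% bootstrap interval 0.06 to 0.08). That length is the one deposited for the gene and need not be that of a single transcript. Reads moved between the gel-forming mucins would keep their sum, and the summed CPM of MUC2, MUC5AC, MUC5B and MUC6 was 681.5 ± 37.0 in wild type and 532.7 ± 87.4 in the knockout-labelled libraries, a ratio of 0.782. This explanation cannot be told apart, because the highest knockout-labelled sum (627.9) lay below the lowest wild-type sum (649.4) by less than either SD, and the others were 456.1 and 514.2 against 673.0 and 722.0. A lower transcription or stability of these mucin RNAs that goes with the label, or with the clone or culture behind it, is a hypothesis that stays open beside it; a loss of single mucin genes was not tested.

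Whether chance can produce counts of this size cannot be settled by regrouping, since 3 libraries against 3 allow only 10 splits. In each case 1 of the 10 splits, the real one, gave as many. It called 3735 genes with edgeR, 936 of them at an absolute log2 fold change of at least 1, and the highest of the other splits called 0 and 0, with 103 to 988 genes at an unadjusted p below 0.05. For gene lists the real split gave 13 calls by camera, and each of the others gave 2 to 5 although it called 0 genes. Camera at the preset correlation thus also called lists in groupings that mix the labels.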
